A study of Homo sapiens with 6 samples.

How the data were processed

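Total RNA of SH-SY5Y, an established human neuroblastoma cell line, was measured on 1 type of Affymetrix microarray, HTA 2.0, per the series' design text. This array measures coding and noncoding RNA through transcript clusters, each a set of probes for the exons of 1 locus. Cells had been stably transfected with an NHEG1 expression vector or with the empty vector and selected with neomycin, per the labels' protocols. Each of the 6 RNA samples was hybridised to its own array, 3 per group. Groups and replicate numbers were taken from the labels. No label states whether the replicates came from separate cultures or separate stable lines, so p-values measure only the spread between these samples, which may be technical.

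The authors deposited 1 table of values for all 6 arrays, and its values are treated here as log2 signal. The log2 scale was inferred from the values: they ran from 1.45 to 14.8, which is the range of log2 signals of this type of scanner. The summarization, background correction, normalization and software used by the authors are not given in the sources used here. The array medians lay between 5.11 and 5.12, while the arrays' distributions were not identical. A difference in total RNA per cell would not show in values whose array medians are this close.

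The table held 70523 features, of which 2995 were control features and were left out of the tests. The other 67528 were transcript clusters. A probe table paired 23781 of these with 1 gene symbol, 1543 with several and 42204 with none. Clusters with several symbols were tested but not named, and clusters with none are unnamed here, not without a gene. DDX5 is not reported because its symbol stood only on a cluster with several symbols. The 1-symbol clusters covered 22465 genes, 479 of them with more than 1 cluster. For gene lists, the cluster with the highest mean over the 6 arrays stood for such a gene. Gene lengths and neighbouring genes were taken from RefSeq genes of assembly GRCh38.p14, which gave a length for 98.7% of these genes. The build of the array's annotation is not given in the sources used here, so no coordinates are printed.

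NHEG1 minus empty vector was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, without trend), two-sided, on the deposited values, and p-values were adjusted by the Benjamini-Hochberg method over all 67528 transcript clusters. The threshold was an adjusted p under 0.05, with a count at 2-fold or more beside it. Adjusted p-values of genes are from this model. Confidence intervals are 95% intervals from the same model. For 3 arrays against 3, the two-sided exact permutation test cannot give a p below 0.1. The number of arrays limits the precision: the median standard error of a log2 difference was 0.074, and the smallest p of all clusters would have had to reach 7.40e-07 to pass alone.

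The design, the 31 gene lists, the rule for named genes and all but 3 of the alternatives were chosen before the data were examined. The rule named NHEG1 first, then a fixed set of genes (DDX5, DDX17, CTNNB1, TCF7L2, LEF1, AXIN2, CCND1, MYC and MYCN), then the leading clusters past the threshold or, with fewer than 5 past it, the 10 clusters with 1 gene symbol and the smallest p, given as values that did not pass. For each list it named up to 4 members past the threshold or, with none, up to 2 with the largest log2 difference, as values. Further members named in the text were chosen after their values were seen.

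Lists were tested with camera (limma), which compares a list with all other genes, at a preset correlation of 0.01 between genes, and adjusted over the 30 lists with at least 5 measured genes. Camera was also run with the correlation estimated from the residuals, and fry (limma) asked whether a list's genes moved, on balance, in 1 direction or changed in either direction. The list of mitochondrially encoded genes had too few measured genes. A list score is the mean deviation of the list's genes from their mean over the 6 arrays. Members were also adjusted over the list alone.

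Alternatives were quantile normalization, median centring, filters on dim features, single-symbol features alone, trended and robust moderation, array weights, the replicate number as a block, leaving out each array in turn, other ways of representing genes and other list tests. An ordinary fit without moderation, removal of each array's trend over gene length, and the list test without NHEG1 replicate 3 at an estimated correlation were added after seeing the data.

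The scripts were tested on simulated data with the real means and limma's estimated spread. With 200 of 67528 clusters changed in each of 10 simulations, limma recovered 41.3% of those changed 1.5-fold, 86.4% of those changed 2-fold and 97.6% of those changed 4-fold. The mean number of unchanged clusters called was 5.6, 8.4 and 10.2. Clusters were simulated as independent, and 200 true changes loosen the cutoff of the adjustment. These shares can therefore overstate the recovery in data with fewer changed clusters. Camera called all 20 simulated lists of 30 genes shifted by 0.1 on the log2 scale and 2 of 20 unshifted lists at an unadjusted threshold, with genes simulated as independent.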

Results

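Gene expression was measured in SH-SY5Y neuroblastoma cells carrying a stable NHEG1 expression vector (3 arrays) or the empty vector (3 arrays). NHEG1, neuroblastoma highly expressed 1, is a long noncoding RNA, and the comparison asks how the transcriptome differs when it is over-expressed. The 6 arrays were alike: the correlation of log2 values across transcript clusters averaged 0.993 within the empty vector group, 0.992 within the NHEG1 group and 0.992 between groups. The clusters are not independent replicates. The first principal component held 30.1% of the variance and set NHEG1 replicate 3 apart, at 36.9 on that axis. The other 5 arrays lay between -22.8 (empty vector replicate 1) and 1.04. On the second component, with 23.3%, the arrays ran from -23.3 (empty vector replicate 2) to 26.1 (empty vector replicate 1).

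NHEG1 itself was measured higher in the cells transfected with it. Its log2 signal was 5.90 ± 0.04 (SD, n = 3) with the empty vector and 6.61 ± 0.10 (SD, n = 3) with NHEG1, a ratio of 1.63-fold (95% confidence interval 1.47 to 1.82). All 3 NHEG1 arrays (6.50, 6.65 and 6.69) lay above all 3 empty vector arrays (5.95, 5.86 and 5.90), and the exact permutation p was 0.1, the smallest possible. The difference of 0.71 (SE 0.065) was larger than the spread between replicates and ranked 2 of 67528 clusters by p. It did not pass the adjustment over all clusters (limma, adjusted p = 0.615).

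No transcript cluster passed the threshold, in either direction and at any fold: 0 of 67528 in limma, with a smallest adjusted p of 0.207. Whatever the p, 41 clusters differed at least 2-fold, 26 higher and 15 lower. At an unadjusted p under 0.05 there were 4616 clusters, 2278 higher and 2338 lower, against 3376.4 that chance gives, and a fit without moderation gave 4591. The 23781 clusters with 1 gene symbol held 1226 of them, 645 higher and 581 lower, against 1189 that chance gives. In this fit over all clusters, most of the excess therefore lay in clusters with no symbol or several. That share depends on the fit. With 1 cluster per gene fitted alone, 875 genes with a length were higher and 974 lower at 0.05, against 1108 that chance gives. Groups did not overlap in 8777 clusters, where chance gives 10% for 3 against 3, or 6752.8; 3557 of them were higher and 5220 lower. At an unadjusted p under 0.001 there were 97 clusters, 70 higher and 27 lower, against 67.5 that chance gives. The smallest p belonged to a cluster with no gene symbol, TC10001389.hg.1, at 4.09 ± 0.08 with the empty vector and 3.00 ± 0.11 with NHEG1 (SD, n = 3). It is named here because it led all clusters.

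After NHEG1, the genes with the smallest p were mostly measured higher with NHEG1, and none passed. THOC2, a subunit of the THO complex of mRNA export, differed by 0.76 (SE 0.092), from 4.70 ± 0.10 to 5.46 ± 0.15 (SD, n = 3). LUC7L3, a splicing factor, differed by 0.48 (SE 0.061), and CLK4, a kinase of splicing factors, by 0.35 (SE 0.047). The transcription factor NFAT5, which acts in the response to osmotic stress, differed by 0.49 (SE 0.067). The kinases TAOK1 and ROCK2 differed by 0.51 (SE 0.076) and 0.39 (SE 0.058), the deubiquitinase USP34 by 0.43 (SE 0.056), and ARFGEF1, an exchange factor of ARF GTPases, by 0.41 (SE 0.054). RNA5SP162, a 5S ribosomal pseudogene, was the one measured lower, by -0.65 (SE 0.088). By mean level among all clusters, ROCK2 was dim, at percentile 20, and USP34 and CLK4 lay at percentile 35. The other genes named here lay between percentile 49 (LUC7L3) and 88 (RNA5SP162). Each of these 9 genes had non-overlapping groups, an exact permutation p of 0.1 and an adjusted p of 0.644 (limma). On the same arrays, the antigenomic background probe sets with 13 to 24 G or C bases, which match no human sequence, were measured lower with NHEG1, at 7.31 ± 0.05 against 7.50 ± 0.05 (SD, n = 3), a difference of -0.19 (exact permutation p = 0.1). The sets with 3 to 9 G or C bases lay near the floor, at 2.23 ± 0.03 against 2.22 ± 0.07 (SD, n = 3; exact permutation p = 0.8).

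**Figure D1:**
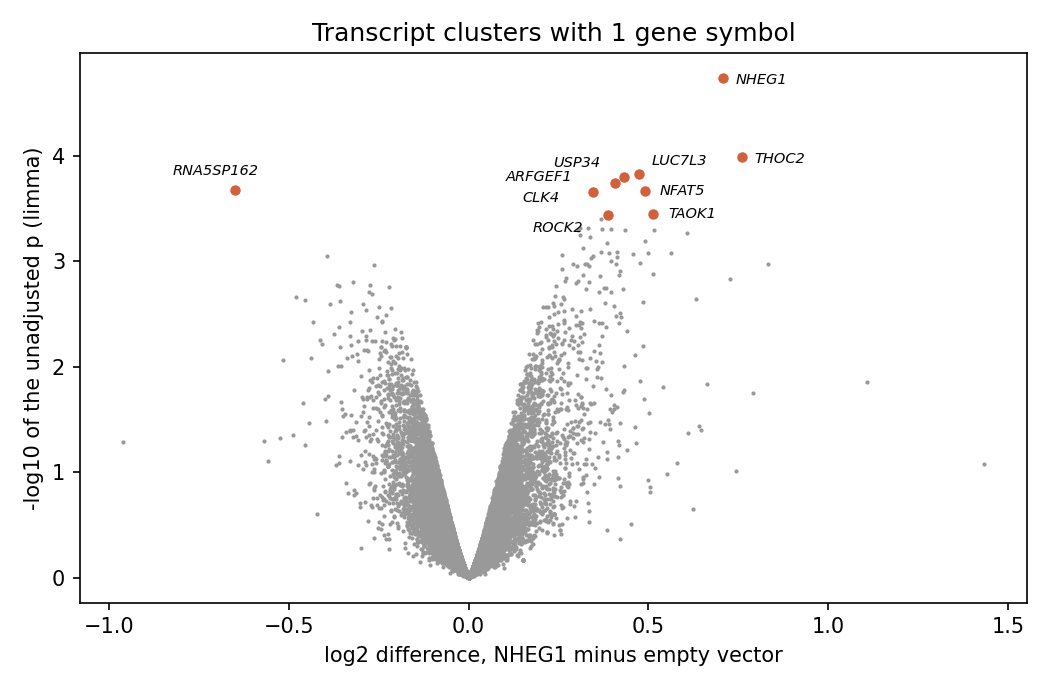
Each point is a transcript cluster with 1 gene symbol: the horizontal axis is the log2 difference, NHEG1 minus empty vector, and the vertical axis is -log10 of the unadjusted p from limma. The 10 with the smallest p are named; 9 lie to the right of 0, RNA5SP162 lies to the left, and none passed the adjusted threshold.

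**Figure D2:**
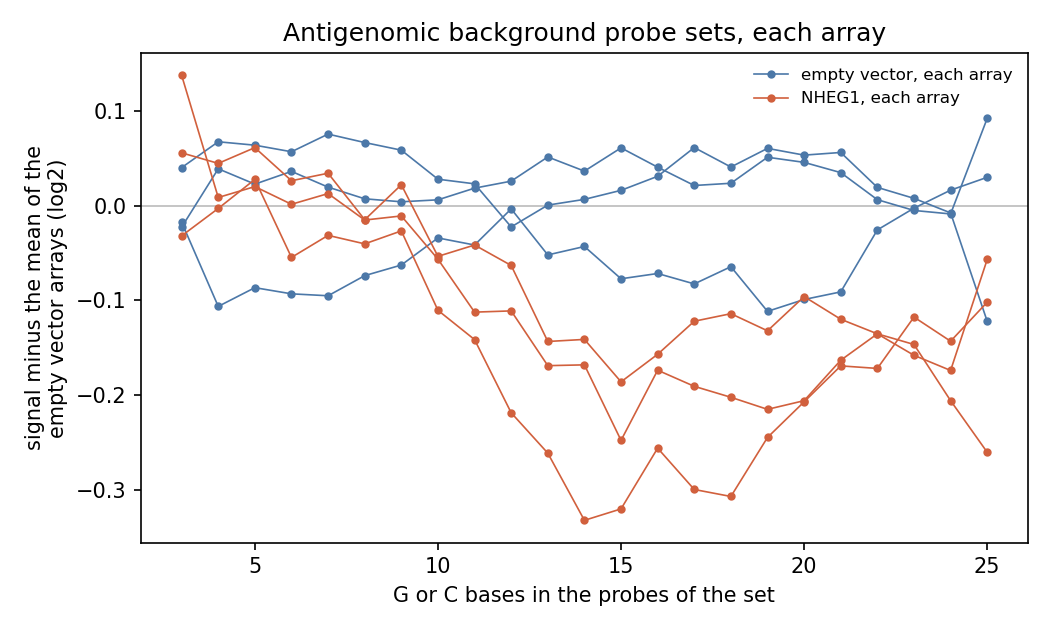
Each line is 1 array: the horizontal axis is the number of G or C bases in the probes of an antigenomic background set, and the vertical axis is the log2 signal minus the mean of the 3 empty vector arrays. In 11 of the 12 sets with 13 to 24 G or C bases all 3 NHEG1 arrays lie under all 3 empty vector arrays. Over all 23 sets this holds for 13, and the arrays overlap in the set with 25.

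The Wnt/beta-catenin, RNA helicase and MYC genes chosen before the data were examined showed small differences, none past the threshold. DDX17, a DEAD-box RNA helicase, was measured at 5.66 ± 0.09 with the empty vector and 5.85 ± 0.05 with NHEG1 (SD, n = 3), a difference of 0.19 (95% confidence interval 0.04 to 0.35; adjusted p = 0.680), with all 3 NHEG1 arrays above. CTNNB1, which encodes beta-catenin, differed by 0.03 (interval -0.10 to 0.17), and its partner TCF7L2 by 0.01 (interval -0.17 to 0.20). LEF1, another transcription factor of the pathway, differed by -0.06 (interval -0.18 to 0.05). Of its target genes, AXIN2 differed by -0.07 (interval -0.18 to 0.04), CCND1, cyclin D1, by -0.05 (interval -0.23 to 0.12) and MYC by -0.04 (interval -0.16 to 0.08). MYCN, the MYC gene amplified in part of neuroblastomas, differed by -0.11 (interval -0.25 to 0.04). All 3 NHEG1 arrays lay below the empty vector arrays for LEF1 and AXIN2, and the arrays overlapped for the other 5. The sign for CTNNB1, TCF7L2 and CCND1 changed under at least 1 alternative, and MYC differed by -0.01 without empty vector replicate 1.

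**Figure D3:**
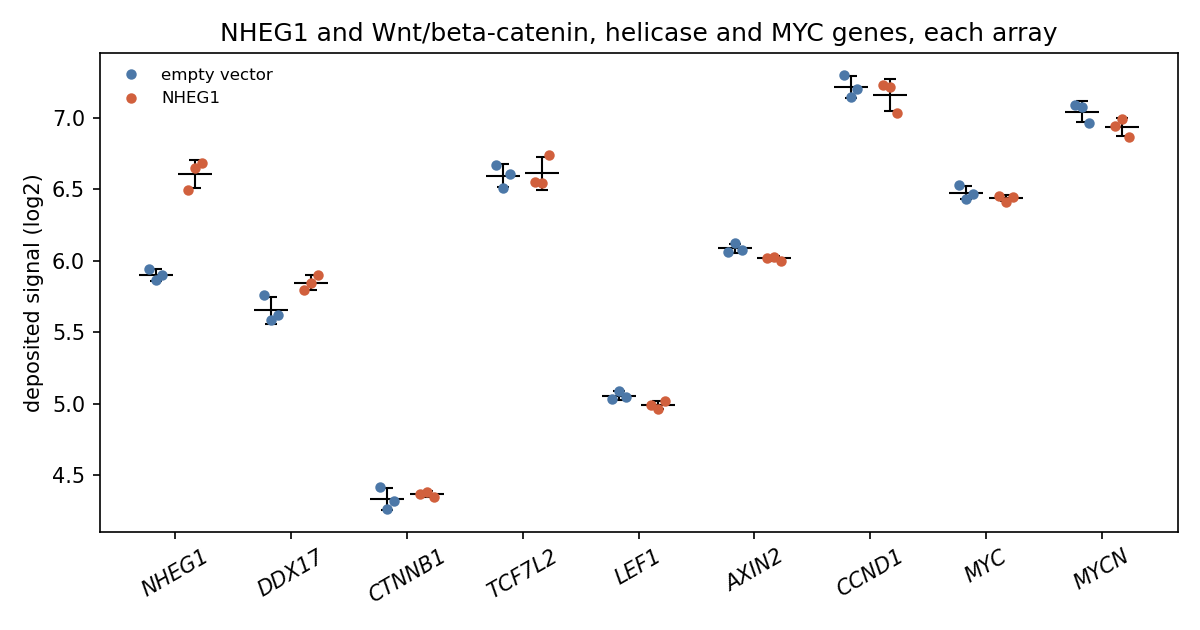
Deposited log2 signal (vertical axis) of NHEG1 and of 8 genes chosen in advance (horizontal axis), with 1 point per array and bars for the mean ± SD of 3 arrays, empty vector in blue and NHEG1 in red. For NHEG1 the groups lie 0.71 apart; for the other genes the difference was at most 0.19.

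The list of Wnt/beta-catenin target genes had 31 of 42 measured members with a negative difference and a mean difference of -0.04. It did not pass camera (adjusted p = 0.0836; 0.751 with an estimated correlation). The largest differences in it were those of SP5 (-0.21, SE 0.073) and APCDD1 (-0.13, SE 0.057). The 65 measured components of the Wnt pathway had a mean of -0.01 (camera adjusted p = 0.815), with the kinases GSK3B at 0.17 (SE 0.063) and CSNK1A1 at 0.17 (SE 0.075). In fry, which asks whether a list's genes move on balance in 1 direction, the components passed, downward (adjusted p = 0.0298), with 40 of 65 negative. Fry does not compare a list with other genes: the mean of the components was -0.011, and the median over all genes was -0.014. The targets passed fry's test of change in either direction (adjusted p = 0.00655). They passed camera downward without NHEG1 replicate 3 (mean -0.04, adjusted p = 0.0494), but not with an estimated correlation there (adjusted p = 0.693). The 26 DEAD-box RNA helicases had a mean of 0.05 (camera adjusted p = 0.0732; 0.781 with an estimated correlation), with DDX3X at 0.40 (SE 0.14) and DDX6 at 0.20 (SE 0.077). The helicases passed camera with array weights (adjusted p = 0.00881), with dim features left out (adjusted p = 0.0263 and 0.0452), over genes of at least the median level (adjusted p = 0.0422), and without empty vector replicate 1 (adjusted p = 0.0120) or NHEG1 replicate 3 (adjusted p = 2.93e-05; mean 0.11). At an estimated correlation the call without NHEG1 replicate 3 was lost (adjusted p = 0.693). Their mean was 0.02 (adjusted p = 0.683) without NHEG1 replicate 2 and 0.03 (adjusted p = 0.172) without NHEG1 replicate 1. Without empty vector replicate 2 it was 0.03 (adjusted p = 0.459).

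Camera called 4 of the 30 lists. The 6 arrays make 10 splits into 3 and 3, and 8 of them, the real one included, gave at least 4 called lists. The highest other split gave 9, so the number of calls does not set the real groups apart. With an estimated correlation between genes, camera called 0. That estimate was 0.43 for glycolysis, 0.27 for oxidative phosphorylation, 0.20 for hypoxia and 0.028 for the adrenergic factors, against the preset 0.01. The adjusted p with it was 0.751 for each, and also for Notch genes, whose estimate was 0.0029. The Benjamini-Hochberg adjustment over the 30 lists can give lists with different p-values the same adjusted p. The shared value therefore does not tell lists apart by their correlation, and their unadjusted p-values are not given here. Fry in 1 direction called none of these 4 (adjusted p = 0.452 for glycolysis, 0.546 for hypoxia, 0.459 for oxidative phosphorylation and 0.119 for the adrenergic factors). Glycolysis genes were higher: 14 of 19 measured members had a positive difference, the mean was 0.08, and the adjusted p was 0.00212 (adjusted p = 0.751 with an estimated correlation). PGK1, phosphoglycerate kinase, was at 7.35 ± 0.21 and 7.67 ± 0.14 (SD, n = 3), and the glucose transporter gene SLC2A1 at 7.38 ± 0.05 and 7.58 ± 0.07 (SD, n = 3). The hypoxia response list, which shares 6 measured genes with it, was higher too, with 21 of 28 members positive and a mean of 0.05 (adjusted p = 0.0419; adjusted p = 0.751 with an estimated correlation). PGK1 differed by 0.31 (SE 0.12) and EGLN1, an oxygen-sensing prolyl hydroxylase, by 0.25 (SE 0.085). Nuclear-encoded genes of oxidative phosphorylation were lower, with 40 of 46 members negative and a mean of -0.05 (adjusted p = 0.0219; adjusted p = 0.751 with an estimated correlation). COX8A, a subunit of cytochrome c oxidase, differed by -0.19 (SE 0.054) and NDUFS7, a subunit of complex I, by -0.15 (SE 0.052). On the same arrays the GC-rich antigenomic sets differed by -0.19. The scores of these 3 lists overlapped between groups, with an exact permutation p of 0.3 for glycolysis, 0.3 for oxidative phosphorylation and 0.2 for hypoxia. Without NHEG1 replicate 3, none of the 3 passed: the adjusted p was 0.270 for glycolysis (mean 0.05), 0.267 for oxidative phosphorylation (mean -0.03) and 0.581 for hypoxia (mean 0.02). Oxidative phosphorylation also failed without empty vector replicate 1 (adjusted p = 0.462; mean -0.03), and hypoxia without empty vector replicate 2 (adjusted p = 0.103; mean 0.04) or 3 (adjusted p = 0.0665; mean 0.05). With array weights hypoxia (adjusted p = 0.0976) and oxidative phosphorylation (adjusted p = 0.0923) failed and glycolysis passed. With a trend over gene length removed both again had an adjusted p of 0.0760, with a mean of 0.06 for hypoxia and -0.03 for oxidative phosphorylation.

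The adrenergic core transcription factors, which hold the sympathetic identity of neuroblastoma cells, were the other list called, downward. Of 23 measured members 20 were negative, with a mean of -0.06 (camera adjusted p = 0.0479, or 0.751 with an estimated correlation). The estimate was 0.028, near the preset 0.01, so the loss does not show that these genes move together. INSM1 differed by -0.20 (SE 0.095; -0.12 without empty vector replicate 3) and HAND1 by -0.19 (SE 0.10; -0.09 without NHEG1 replicate 3). All 3 NHEG1 arrays scored below the empty vector arrays (exact permutation p = 0.1), which 10 of the 30 lists showed, the mesenchymal, epithelial, and Schwann cell and glial lists among them. The reverse held for 0 lists. The median over all genes was -0.014, so most genes were negative, and counts of negative members stand against that. The adrenergic list was affected by the choice of arrays and settings. The call was lost without empty vector replicate 2 (adjusted p = 0.143; mean -0.05), empty vector replicate 3 (adjusted p = 0.0665; mean -0.05) or NHEG1 replicate 1 (adjusted p = 0.0999; mean -0.06). It passed in 5 of 15 other settings. Among these 5, single-symbol features alone repeats the reported list test, because the lists used only such clusters. The call was also lost with quantile normalization (adjusted p = 0.0877), median centring (adjusted p = 0.0567) and array weights (adjusted p = 0.0588). The replicate block (adjusted p = 0.0627) and the filter at the 25th percentile (adjusted p = 0.0579) lost it too. The same held for the mean of a gene's clusters (adjusted p = 0.0557) and fry (adjusted p = 0.119). With the trend over gene length removed the adjusted p was 0.0760. The mean lay between -0.06 and -0.04 in all settings that lost the call. The list of mesenchymal neuroblastoma markers, the alternative cell state, had a mean of -0.01 over 43 members with camera's direction upward (adjusted p = 0.605). It passed fry's test of change in either direction (adjusted p = 0.0224): ID1, an inhibitor of helix-loop-helix factors, differed by -0.29 (SE 0.10; -0.18 without NHEG1 replicate 3) and FN1, fibronectin, by 0.19 (SE 0.046). The catecholamine list had 18 of 21 members negative and a mean of -0.04. It passed fry downward (adjusted p = 0.0240) but not camera (adjusted p = 0.0846), with SCG5 at -0.12 (SE 0.062; -0.07 without empty vector replicate 1) and PNMT at -0.10 (SE 0.074; -0.05 without NHEG1 replicate 3).

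Over all 30 lists, 0 members passed over all clusters and 0 passed when adjusted over the list alone. Lists of other cell types were also not called by camera: Schwann cell and glial markers had a mean of -0.03 (adjusted p = 0.531), epithelial markers -0.03 (adjusted p = 0.376), fibroblast markers -0.01 (adjusted p = 0.992), and endothelial and leukocyte markers -0.01 with camera's direction upward (adjusted p = 0.998). The fibroblast markers did pass fry's test of change in either direction (adjusted p = 0.00655), as the Wnt/beta-catenin targets did.

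**Figure D4:**
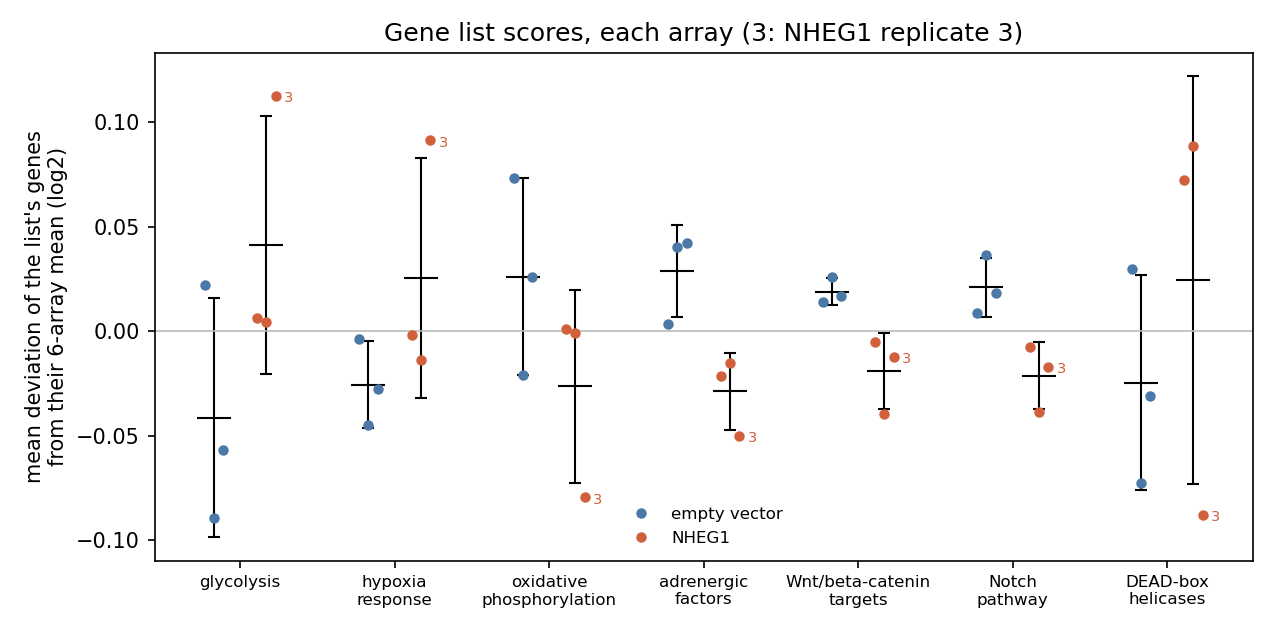
Mean deviation of each list's genes from their mean over the 6 arrays, on the log2 scale (vertical axis), for 7 lists (horizontal axis), with 1 point per array and bars for the mean ± SD of 3 arrays, empty vector in blue and NHEG1 in red. NHEG1 replicate 3, marked 3, has the highest glycolysis and hypoxia scores (0.11 and 0.09) and the lowest oxidative phosphorylation score (-0.08).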

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

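The trend over gene length, the fit without moderation and the list test that joins a left-out array with an estimated correlation were added after seeing the data. The count of changed transcript clusters was 0 under every alternative, with or without 2-fold, and 0 of the 74 followed genes passed under any (smallest adjusted p 0.162); the sign of 6 changed in at least 1. The NHEG1 difference stayed between 0.67 and 0.76. The number of lists called, 4 as reported, was 2 with array weights (glycolysis and DEAD-box helicases), 0 with an estimated correlation, 2 with fry (Wnt pathway components and catecholamine genes, none of the 4) and 1 (glycolysis) with the trend over gene length removed, and the cause was not tested. It ranged from 2 to 8 when 1 array was left out, and was 0 without NHEG1 replicate 3 at an estimated correlation. Without NHEG1 replicate 3, the list of G1/S and DNA replication turned upward and passed (mean 0.032, adjusted p = 0.0440), while without NHEG1 replicate 2 it passed downward (mean -0.050, adjusted p = 0.0463); its adjusted p under the other alternatives ran up to 0.998. The replicate numbers did not pair the arrays: deviations of arrays with the same number correlated at -0.051, -0.14 and -0.043. With the replicate block, 3 lists were called, 0 clusters passed (smallest adjusted p 0.854) and the NHEG1 difference was 0.71. A second pseudocount was not run, because the values are on a log scale. Dim features have less signal over background; leaving out those under the median level gave 0 clusters and 5 lists.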

Other observations

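Of the remaining lists none passed camera as reported. Notch pathway genes came closest, with 23 of 26 members negative, a mean of -0.04 (adjusted p = 0.0732; adjusted p = 0.751 with an estimated correlation) and all 3 NHEG1 arrays scoring below the empty vector arrays, as in 10 of the 30 lists. HES4, a Notch target, differed by -0.12 (SE 0.052) and NRARP by -0.13 (SE 0.12; -0.05 without NHEG1 replicate 3), and the list passed fry's test of change in either direction (adjusted p = 0.000307). Cholesterol and fatty acid synthesis had 23 of 27 members negative (mean -0.04, adjusted p = 0.0846), with SCD at -0.14 (SE 0.048) and ACLY at -0.20 (SE 0.13; -0.04 without NHEG1 replicate 3). That list passed with features under the 25th percentile left out (adjusted p = 0.0345) and over genes of at least the median level (adjusted p = 0.0452), both with all 6 arrays. It did not pass with an estimated correlation (adjusted p = 0.751) or without NHEG1 replicate 3 (mean -0.01, adjusted p = 0.544). The unfolded protein and amino acid stress response had 25 of 32 negative (mean -0.04, or -0.02 without NHEG1 replicate 3; adjusted p = 0.112), with SHMT2 at -0.17 (SE 0.069) and CEBPG at -0.11 (SE 0.047). Immediate early genes had a mean of -0.03 (adjusted p = 0.264), with IER5 at -0.16 (SE 0.071; -0.09 without NHEG1 replicate 3) and EGR3 at -0.13 (SE 0.049).

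Means lay nearer 0 for neuronal differentiation and synapse genes (-0.02, adjusted p = 0.531), among them ELAVL2 at 0.24 (SE 0.064) and UCHL1 at -0.11 (SE 0.053), and for p53 targets (-0.03, adjusted p = 0.259), apoptosis regulators (-0.02, adjusted p = 0.531), NF-kappaB and inflammatory genes (-0.02, adjusted p = 0.531) and the interferon response (-0.01, adjusted p = 0.998). Cytosolic ribosomal proteins had a mean of -0.03 (adjusted p = 0.709), G1/S and DNA replication genes -0.02 (adjusted p = 0.541), and replication-dependent histones -0.08 over 16 measured of 80 listed genes (adjusted p = 0.595). Without NHEG1 replicate 3 these means were 0.01, 0.03 and 0.06, and those of apoptosis regulators and antigen presentation -0.01 and -0.03. For epithelial-mesenchymal transition and invasion, camera's direction was upward while the mean was negative (mean -0.0045, adjusted p = 0.815). The same held for G2/M and mitosis (mean -0.0046, adjusted p = 0.815) and antigen presentation (mean -0.0052, adjusted p = 0.965). It also held for collagens, laminins and basement membrane (mean -0.0033, adjusted p = 0.992). Camera compares a list with other genes, and the median over all genes was -0.014. The interferon (mean -0.0094) and fibroblast lists (mean -0.0091) lay above that median too, with camera's direction downward. For MYC and MYCN targets of ribosome biogenesis the mean was 0.00050 and the median -0.0074 (adjusted p = 0.992). COL1A1 differed by 0.18 (SE 0.054) and DCN by -0.19 (SE 0.072), while a second cluster of DCN differed by 0.04, and both the collagen list (adjusted p = 0.0143) and the fibroblast list (adjusted p = 0.00655), which share 6 genes, passed fry's test of change in either direction. Without NHEG1 replicate 3, further lists passed upward: G2/M and mitosis had a mean of 0.06 (adjusted p = 2.93e-05), MYC and MYCN targets of ribosome biogenesis 0.05 (adjusted p = 0.00427) and DEAD-box helicases 0.11 (adjusted p = 2.93e-05), while immediate early genes (-0.06, adjusted p = 0.00427), Notch genes (-0.04, adjusted p = 0.0440) and Wnt/beta-catenin targets (-0.04, adjusted p = 0.0494) passed downward. With an estimated correlation none of them passed without that array (adjusted p = 0.693 for each). NHEG1 replicate 3 had the lowest score of the 6 arrays for G2/M (-0.12), G1/S (-0.12) and MYC and MYCN targets (-0.11). It was also the lowest for DEAD-box helicases (-0.088), cytosolic ribosomal proteins (-0.087) and replication-dependent histones (-0.32).

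In the patterns below, all tests except the split counts of called clusters and lists were chosen only after the result was seen; those of long genes on the trend and on the other splits were chosen after the pattern but before their own values were seen. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For changed clusters, with or without 2-fold, the count tests nothing: the real split gave 0 and the highest other 0, so all 10 reach it. For called lists, 8 of the 10 gave at least the real 4, and the highest other split gave 9. For clusters at an unadjusted p under 0.05, 1 of the 10, the real one, reached 4616, and the highest other split gave 4554; that split sets empty vector replicate 1 and NHEG1 replicates 1 and 2 against the rest.

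The first pattern is that long genes were measured higher with NHEG1: of the 36 genes at an unadjusted p under 0.001, where chance gives 22.2, 34 were higher, with a median gene length of 110622 bases against 18289 for all genes with a length, among them UPF2 (0.32), SMG1 (0.31) and ATRX (0.46), named after their values were seen. The imbalance was smaller at wider thresholds, with 184 higher and 80 lower at 0.01 and 619 higher and 528 lower at 0.05. A trend of each array's signal over gene length as the whole cause is argued against for the smallest p: with 1 cluster per gene fitted alone, 71 were higher and 13 lower at 0.001 before it was removed and 71 and 4 after (median length 95945), with 0 past the adjusted threshold, while at 0.05 the median length of the higher genes went from 44274 to 24824, so for that wider set it stays open. An axis of variation unrelated to the group stays open: the highest other split with long genes gave 11 in 1 direction, but 10 splits are too few to exclude it, and NHEG1 replicate 3 had a correlation with log10 gene length (-0.016, across genes) closer to those of the empty vector arrays (-0.083 to -0.055) than to those of NHEG1 replicates 1 and 2 (0.15 and 0.10). GC-dependent hybridization could contribute and cannot be told apart here because the GC content of the probes was not analysed: genes of chromosome 19, which is rich in G and C, had the lowest median of the 23 chromosomes compared, 1 to 22 and X (-0.041), and a response of the cells to NHEG1 stays open, untested.

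The second pattern is the lower signal of GC-rich antigenomic probe sets on the NHEG1 arrays. A lower overall signal of those arrays cannot be told apart from other causes: the sets with 3 to 9 G or C bases differed by 0.011, but they lie near the floor. Labelling, hybridization or scanning that differed between the groups could give the 11 of 12 sets with non-overlapping arrays, and no label gives a batch that would separate this from the group. Poly-A controls, which are added before labelling, had a median that differed by -0.26, with all 3 NHEG1 arrays below by the median but overlapping by the mean, ERCC spike sequences one that differed by -0.13, overlapping by the median but not by the mean, and hybridization controls one that differed by -0.02, with overlapping arrays. No biological explanation was tested for probes that match no human sequence.

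The third pattern is the higher glycolysis and hypoxia lists with the lower oxidative phosphorylation list. The state of NHEG1 replicate 3 alone is a candidate explanation: without it the smallest adjusted p of the 3 lists in camera was 0.267. That array had the lowest weight of the 6 (0.635), though empty vector replicate 1 was close (0.696). The oxidative phosphorylation call was also lost without empty vector replicate 1 (mean -0.03 against -0.05), and the hypoxia call without empty vector replicate 2 or 3, where its mean was 0.04 and 0.05 against 0.05. Genes that move together between arrays whatever the group may also account for the calls. Their estimated correlation was 0.43 for glycolysis, 0.27 for oxidative phosphorylation and 0.20 for hypoxia, against the preset 0.01. With it the smallest adjusted p in camera was 0.751. That value cannot decide this, because the Benjamini-Hochberg adjustment can give lists with different p-values the same adjusted p. The Notch list, with an estimate of 0.0029, also had 0.751. A metabolic response to NHEG1 stays open, untested.

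Medians over windows of 60 neighbouring genes, 620 in all, ran from -0.073 on chromosome 19 to 0.029 on chromosome 18.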
